A study of Rattus norvegicus with 6 samples.

How the data were processed

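Messenger RNA was measured in cultured rat oligodendrocyte precursors before and after differentiation, on 1 single-colour array per sample. Per the labels' protocols, total RNA was amplified with an amino allyl kit and coupled to the dye Cy5 by a Toray procedure. The label values place 3 arrays in the group before differentiation and 3 in the group after it. The tag names printed beside those values speak of lymphocytes and of a switching experiment, which neither the values nor the sample source repeat, so the groups rest on the values. Titles count time as day or DIV, 0 before and 3 after. The 4 arrays titled DIV carry the replicate numbers 1 and 2. The pair titled day carries no number and was named replicate 3 because both titles share their form. Nothing in the labels says that the samples came from separate cultures or animals, so p-values measure only the spread between these samples, which may be technical.

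Per the file headers, each deposited scanner table gives the median intensity of every spot at 635 nm and the median intensity around it, with scans at 3 gain settings related by straight lines. The headers state no background subtraction or normalisation of these intensities. The deposited table of processed values holds intensity on a linear scale, and the method the authors used for it is not given in the sources used here. Set against the scanner values, each of its columns equalled the spot intensity minus a constant near the blank spots, times a factor. That factor puts the median of the values that are not empty at 25 in every column. Values were empty where a spot carried a bad flag or lay below a limit, which was rebuilt as the mean of the blank spots plus 2 SD after trimming 5% at each end. That limit accounted for every empty value, although up to 56 values per array lay below it. The largest relative difference between the rebuilt and the deposited values was 1.57%. Scale and direction of the table are therefore known from the values, and no centring of genes was found.

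The array holds 20174 gene spots with 1 Ensembl rat gene ID each, 5808 blank spots and 809 positions without a probe, besides control spots. A gene counted as above background on an array where its signal exceeded the mean of the blank spots plus 2 SD, and it was tested if this held on at least 3 of the 6 arrays. That left 14237 genes. The spot signal was corrected with the normexp method over all spots with an offset of 50, control spots were then removed, and the arrays were quantile normalised and taken to log2. The 5 gene spots with a bad flag, all on the array after 1, were treated as missing. Differences, after minus before, were tested two-sided with lmFit and eBayes of limma 3.58.1 in R 4.3.3, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. An offset compresses the fold change of dim genes. The number of arrays limits the precision of every value.

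The groups, the test, the filter, the offset, the rule for named genes and most alternatives were set before the data were examined. The design did not say whether normexp would use the intensity around the spots. Its rank correlation with the spot signal lay between 0.904 and 0.944 across the arrays, and because it tracked the signal it was left out of the main setting. This choice was made after those correlations were seen and before any gene was tested. A check made after the tests took 17468 gene spots with 4 adjacent spots and subtracted the mean log2 of these from both columns. On these spots the rank correlation was 0.923 to 0.970 before this step and 0.961 to 0.990 after it. The intensity around a spot correlated at 0.108 to 0.238 with that around adjacent spots. Variation shared by adjacent spots therefore does not account for the relation. The opposite choice is given as an alternative chosen after seeing the data, and it ended nearly all calls.

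Gene symbols were needed for 35 gene lists, for a set of key genes and for the rule on named genes, which took genes with a symbol, an adjusted p under 0.05 and groups that did not overlap, in order of the size of the change. The files do not pair the gene IDs with symbols. The reference table of 47357 genes used here held no Ensembl ID, and 0 of the 20174 IDs matched. The gene lists and key genes were therefore not tested, and the clause on symbols was dropped. Only the 2 largest rises and the 2 largest falls are named, by ID.

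Alternatives covered scaling, background correction, offset, the authors' values, the filter, the variance model, array weights, a fold minimum, blocks and the omission of each array. The mean over the probes of a gene was not run because each gene has 1 probe. To check whether replicate numbers pair the arrays, the deviations of each array from its group mean were correlated across genes. The correlation was 0.269 for replicate 1, 0.478 for replicate 2 and 0.597 for replicate 3, and each array correlated best with its own number. Unmatched numbers among the DIV arrays also correlated positively, at 0.129 for before 2 with after 1 and 0.169 for before 1 with after 2. The deviations carry the difference between day and DIV arrays as well, so the value for replicate 3 may come from the title form. The check is therefore weak for numbers 1 and 2. All 3 exceeded the level set for pairing, so the numbers were taken to pair the arrays on this limited evidence from the data. The model was tested on simulated data for the same 14237 genes, with 50 genes changed at each size. The changed genes were drawn only from brighter genes, so recovery of dim genes was not simulated. Noise was drawn independently for each array, without differences shared by title form or replicate number, so the real arrays may give other rates. The model recovered 76% of genes raised by 2 on the log2 scale and 26% of those raised by 1. It recovered 82% of genes at -2 and 16% at -1, and 6 unchanged genes were called. These sizes were set before the offset was added. The median fitted differences were 1.69 and 0.75 for the rises and -1.63 and -0.79 for the falls. The noise, also set before the offset, took its spread from values with the offset. It may therefore be too small and the rates too high.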

Results

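Oligodendrocyte precursors are glial cells that mature into oligodendrocytes, the myelin-forming cells of the central nervous system. The study compared their messenger RNA before and after differentiation in culture, with 3 arrays in each group. Between 12367 genes (61.3%, before 2) and 15229 genes (75.5%, after 3) of the 20174 on the array lay above background. The median gene signal ranged from 26.4 on after 1 to 38.9 on before 3, against a mean of 12.8 to 15.6 for blank spots. The brightest gene on each array reached 43395 to 58316. Negative control spots exceeded the background limit in 1.04% of cases on after 2 and in 29.2% on after 3, so a dim gene just past that limit is not surely expressed.

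In the main setting a small share of the tested genes was called, and more of them rose than fell. The count depends on the setting and on the power of 6 arrays, so it is not the number of genes that changed. Of 14237 genes tested, 134 rose and 64 fell after differentiation (limma, Benjamini-Hochberg adjusted p under 0.05), together 1.39% of the genes. Among them, 47 rose at least 4-fold whereas 1 fell by as much, and the median log2 difference was 1.41 for the genes that rose and -0.89 for those that fell. These sizes depend on the offset: called genes with at least a 4-fold rise or fall numbered 88 and 8 with an offset of 16 and 163 and 28 with an offset of 1 (chosen after seeing the data), with largest falls of -3.34 and -4.53 on the log2 scale. They numbered 93 and 11 without background correction and 204 and 45 with the authors' values, settings that change other steps too, with largest falls of -3.41 and -5.25. With the offset kept, they numbered 54 and 7 with an intensity trend, 55 and 5 with array weights and 36 and 2 with median scaling. They fell to 25 and 1 without the filter on dim genes. With the intensity around each spot as background (chosen after seeing the data) they fell to 2 and 1. Without before 1, before 2, before 3, after 1, after 2 or after 3, there were 1, 10, 9, 40, 23 and 10 such rises and 1, 1, 2, 6, 1 and 1 such falls, in that order. The genes that rose took 0.450% ± 0.042 of the summed gene signal before and 2.87% ± 0.58 after (SD, n = 3). The genes that fell went from 0.443% ± 0.026 to 0.215% ± 0.018 (SD, n = 3). Both shares describe genes selected for their change on the same arrays.

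Higher genes made up 67.7% of the calls with quantile normalisation, with an exact 95% binomial interval of 60.7 to 74.1%. This interval and the next treat genes as independent, which they are not. With quantile normalisation kept, the share ranged from 50% without before 1 (1 higher, 1 lower) to 91.7% without after 3 (22 higher, 2 lower). With the arrays scaled to 1 median instead, 87 genes were higher and 68 lower, a share of 56.1% with an interval of 47.9 to 64.1% that includes an equal split. The direction turned there without before 3, with 57 higher and 120 lower genes (32.2% higher). In all 198 called genes the values of the groups did not overlap. Over all tested genes, 2754 (19.3%) had groups that did not overlap, 1443 of them higher and 1311 lower after differentiation, where chance gives 10% with 3 against 3 exchangeable arrays. These arrays are not exchangeable: setting before 1, before 2 and after 1 against the rest gave 2838 such genes (19.9%), more than the real groups. The 3 other divisions that part all replicate pairs gave 2.63%, 3.07% and 6.33%. The main fit, set before the pairing was checked, used no block. With the replicate number as a block, limma called 181 higher and 88 lower genes, which included 123 of the 198. At an unadjusted p under 0.05, limma found 2005 genes, 1061 higher and 944 lower, against 712 by chance. Without before 1, before 2, before 3, after 1, after 2 or after 3, limma called 1, 18, 17, 119, 48 and 22 higher genes and 1, 9, 8, 30, 17 and 2 lower genes, in that order. With the intensity around each spot used as background, an alternative chosen after seeing the data, 4 genes were higher and 1 lower, and 189 of the 198 called genes kept their direction.

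The largest rise among called genes was that of ENSRNOG00000016516. Its log2 signal went from 6.85 ± 0.51 before to 14.71 ± 0.58 after (SD, n = 3). The difference of 7.86 (SE 0.38), a 232-fold rise with the offset included, had a Benjamini-Hochberg adjusted p of 0.00807 in limma, and the 3 replicate pairs gave 6.87, 7.99 and 8.72. Its size depends on the setting. The log2 difference was 8.85 with the authors' values, 8.76 with an offset of 1 and 6.46 with the intensity around each spot as background. On the scale of the authors' values, this gene lay between 17.5 and 64.1 before and between 10756 and 21531 after. The median of the values that are not empty is 25 on each array of that scale. ENSRNOG00000016516 alone took 0.380% ± 0.134 of the summed gene signal after differentiation, against 0.000806% ± 0.000354 before (SD, n = 3). The next largest rise was that of ENSRNOG00000002419, from 7.41 ± 0.12 to 14.06 ± 0.79 (SD, n = 3), a log2 difference of 6.65 (SE 0.40, adjusted p 0.00972, limma with Benjamini-Hochberg adjustment). Its pairs gave 5.67, 6.92 and 7.35. The authors' values, an offset of 1 and the intensity around each spot as background gave 7.15, 7.14 and 5.88. Both genes were above the blank limit on all 6 arrays. ENSRNOG00000016516 was dimmest on before 3, at 17.5 on the scale of the authors' values. On that array 18.75% of negative control spots also exceeded the limit, so passing it does not surely give a measured starting level.

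In the main setting, the largest fall among called genes was that of ENSRNOG00000010688, from 9.56 ± 0.06 to 6.73 ± 0.31 on the log2 scale (SD, n = 3). The difference was -2.83 (SE 0.17, adjusted p 0.00972, limma with Benjamini-Hochberg adjustment), and the pairs gave -2.81, -2.47 and -3.21. ENSRNOG00000003442 was next, from 8.38 ± 0.43 to 6.49 ± 0.09 (SD, n = 3), a difference of -1.88 (SE 0.22, adjusted p 0.0347, limma with Benjamini-Hochberg adjustment) with -1.90, -2.24 and -1.51 in the pairs. With the offset included these are falls of 7.10-fold and 3.69-fold, sizes that the offset reduces. The authors' values gave log2 differences of -3.70 for ENSRNOG00000010688 and -2.87 for ENSRNOG00000003442, and an offset of 1 gave -3.67 and -2.79. In both settings another called gene fell further than either. With cyclic loess, the filter on all 6 arrays, the intensity trend or either block, other called genes fell further than ENSRNOG00000003442, so these ranks are those of the main setting. Both genes were above background on all 6 arrays. The symbols of the 4 genes are not paired with their IDs in the files. Over the 21 alternatives the adjusted p ranged from 1.86e-06 to 0.189 for ENSRNOG00000016516, from 2.38e-06 to 0.134 for ENSRNOG00000002419, from 1.80e-04 to 0.128 for ENSRNOG00000010688 and from 9.47e-04 to 0.211 for ENSRNOG00000003442, and no direction changed.

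**Figure D1:**
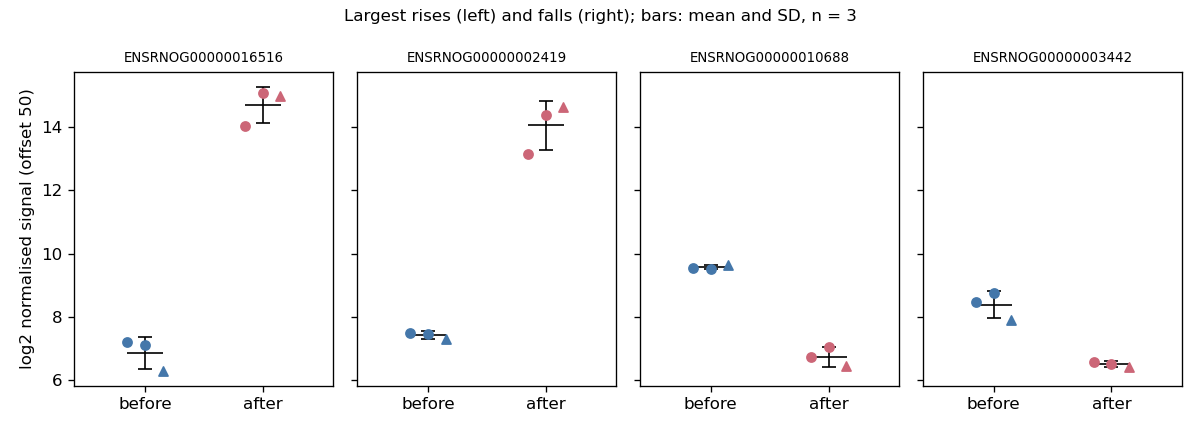
Normalised signal of the 4 named genes on each array, on a log2 axis that includes an offset of 50, before (blue) and after (red) differentiation; circles are arrays titled DIV, triangles arrays titled day, and bars give the mean and SD of 3 arrays. The panels on the left show the 2 largest rises and those on the right the 2 largest falls among called genes in the main setting, and in each panel the groups do not overlap.

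Some genes were above background in 1 group only. On all 3 arrays after differentiation and on none before it, 49 genes exceeded the limit, and 6 of these passed the limma test. The reverse held for 17 genes, of which 0 passed the limma test at the Benjamini-Hochberg threshold. The median log2 difference was 0.29 for the genes detected after only and -0.17 for those detected before only. A further 12026 genes were above background on all 6 arrays and 4304 on none. Other divisions of the 6 arrays into 3 and 3 gave between 1 and 528 genes in place of 66. The division with 528 set before 1, before 3 and after 3, the arrays with the most genes detected, against the rest. Another division that keeps a replicate pair together gave 72, while the 3 other divisions that part all pairs gave 1, 7 and 26.

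The first principal component of the tested genes held 46.2% of the variance and separated before (-36.1 to -14.4) from after (15.3 to 31.7). The second, with 31.8%, separated the pair titled day (-26.9 and -27.5) from the arrays titled DIV (3.80 to 20.6). Across genes, which are not independent replicates, arrays of 1 group and 1 title form correlated at 0.980 to 0.991. Arrays of 1 group with different titles correlated at 0.966 to 0.979, and arrays of different groups with 1 title form at 0.958 to 0.976. Arrays that differed in both correlated at 0.936 to 0.956. In the model with both terms, limma called 474 genes higher and 479 lower on the day arrays (Benjamini-Hochberg adjusted p under 0.05).

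**Figure D2:**
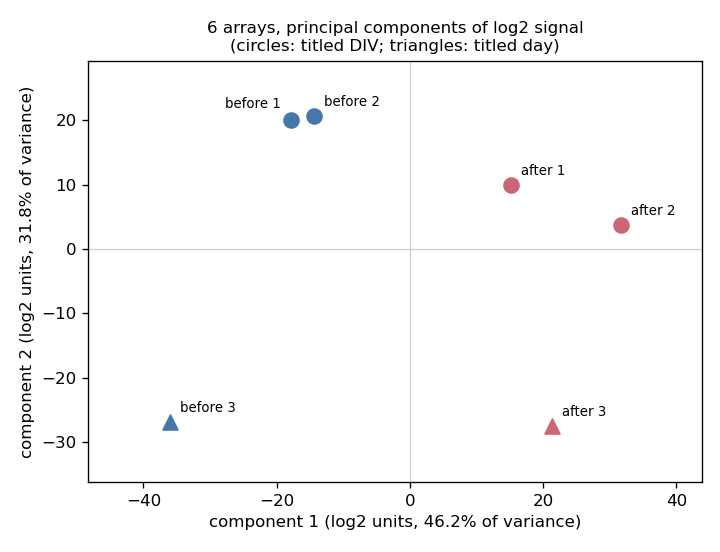
Positions of the 6 arrays on the first 2 principal components of log2 signal, in log2 units, with circles for arrays titled DIV and triangles for arrays titled day; blue is before and red after differentiation. The horizontal axis (46.2% of the variance) parts before from after, and the vertical axis (31.8%) parts the day pair from the DIV arrays.

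Because the title forms mark a possible batch that holds both groups, the differences were also taken within each. Nearly all genes with large differences in the DIV arrays had the same direction in the day pair, and these sets share no array and were normalised separately. Among the DIV arrays, 238 genes were at least 2-fold higher after differentiation with groups that did not overlap, and 237 of these (99.6%) were also higher in the day pair, 193 of them at least 2-fold. Of 102 genes at least 2-fold lower without overlap in the DIV arrays, 102 were lower in the day pair, 67 of them at least 2-fold. Over all tested genes, 53.0% were higher in the day pair. The differences correlated across 14237 genes with Pearson's r of 0.703 and Spearman's rho of 0.546, where genes are not independent replicates. Each of the 198 called genes had the same direction in both sets, which helped to select them. With the title form as a block, limma called 245 higher and 169 lower genes, including 191 of the 198. The DIV arrays alone gave 0 calls in limma, with a smallest adjusted p of 0.104 (Benjamini-Hochberg), and 1926 genes at an unadjusted p under 0.05, 937 higher and 989 lower. The day pair has no replicate and no test of its own. A limma test of whether the change differed between the sets called 0 genes, with 624 at an unadjusted p under 0.05, and it assumes that the lone day arrays vary like the DIV arrays.

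**Figure D3:**
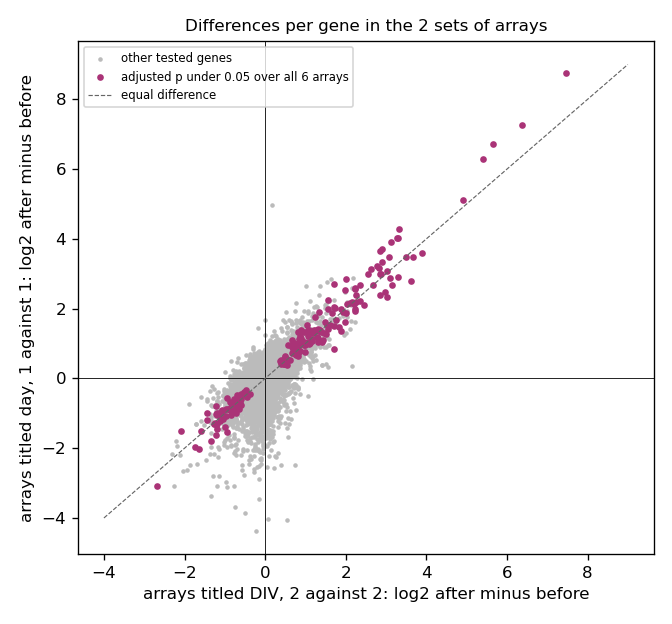
Log2 difference after minus before for each tested gene in the arrays titled DIV (horizontal axis) and in the pair titled day (vertical axis), with called genes of the 6-array comparison in purple, other tested genes in grey and a dashed line at equal differences. All 198 called genes lie in the quadrants of equal direction and scatter around the dashed line.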

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

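All comparisons of control spots in this part were chosen only after their signals were seen. Spots that the files call QC probes lie outside the gene measurement, and their identity is not given in the sources used here. Of 521 such spots, 227 exceeded the blank limit on all 6 arrays. For a limma test they were scaled to the median gene signal of each array, whereas genes were quantile normalised. The 293 spots tested, in a fit of their own, gave 0 calls after Benjamini-Hochberg adjustment and 23 at an unadjusted p under 0.05. Their median log2 difference was -0.02. Because the steps differ, these spots are not a like-for-like control for the gene calls.

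Spots of the kind named Positive Control 1 were dimmer after differentiation in each replicate pair before normalisation, with log2 differences of -0.49, -1.19 and -0.22. The pair of replicate 2 stood out with -1.19. Positive Control 2 gave -0.29, -0.32 and -0.39, and the median gene signal above blank gave -0.57, -0.19 and -0.17. What these controls hybridise to is not given in the sources used here, and no explanation was tested.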

How the results depend on the processing

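The local background, the offset of 1 and the trimmed blank limit were tests chosen only after the result was seen. Higher and lower genes numbered 258 and 107 without background correction, 300 and 107 with an intensity trend and robust estimation, 251 and 147 with array weights, 245 and 169 with the title form as a block and 368 and 158 with an offset of 1. They fell to 69 and 37 without a filter, where 20174 genes were tested, to 4 and 1 with the local background and to 0 and 0 on the DIV arrays alone (limma; 1926 at an unadjusted p under 0.05), where 4 arrays remain. Higher genes numbered 87 with median scaling, 229 with an offset of 16 and 266 with the authors' values, beside 68, 95 and 77 lower genes. A minimum of 2-fold left 29 lower genes. Leaving out each array in turn gave 1 to 119 higher and 1 to 30 lower genes, lowest without before 1. Apart from the smaller designs and the added minimum, the cause was not tested. With the replicate block the counts were 181 and 88, with 123 of the 198 calls shared, and no named gene lost its call. Cyclic loess, the filter on all 6 arrays and the trimmed limit moved the counts less (152 and 68, 144 and 67, and 111 and 53). With the trimmed limit, 36 genes were detected after only and 20 before only. The 198 called genes kept their direction under every alternative that gave them a value, except for 189 of 198 with the local background. ENSRNOG00000016516 and ENSRNOG00000002419 stayed past the threshold in 18 of 21 alternatives, ENSRNOG00000010688 in 19 and ENSRNOG00000003442 in 13, and none reversed. Gene list tests (camera with preset or estimated correlation or on ranks, and fry) were not run for want of symbols, nor was the mean of several probes, as each gene has 1. Signal over background limits the dimmest genes: 4304 exceeded the limit on no array.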

Other observations

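The tests of normalisation and offset, the omissions within them and the log2 falls per pair in this part were chosen only after the result was seen. When the tested genes were divided into 3 equal groups by mean signal, 11 called genes in the dimmest group rose and 2 fell. In the middle group 51 rose and 25 fell, and in the brightest 72 rose and 37 fell.

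More genes rose than fell, 134 against 64, and shares of higher genes are given with exact 95% intervals that treat genes as independent, which they are not, and with the range over the omission of each array. The offset of 50 as the whole cause is argued against by the authors' values, which carry no offset and gave 77.6% (266 of 343, interval 72.8 to 81.9%, 63.9 to 88.1% over omissions). The same values, scaled to a common median, kept more rises without quantile normalisation, but they change the offset and the filter too. Cyclic loess in its place gave 69.1% (interval 62.5 to 75.1%, 66.7 to 89.6% over omissions). It is a weak test, because it also evens out differences between arrays along the signal range. Scaling by medians with the offset kept gave 56.1% (interval 47.9 to 64.1%), which includes an equal split. That share was 32.2% without before 3 (57 higher, 120 lower) against 67.6 to 86.4% when any other single array was left out. Quantile normalisation, as a part or as the whole cause, therefore stays open, and so does differentiation itself, the difference the design names.

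The replicate 1 pair showed smaller changes than the others: for genes at least 2-fold changed in both other pairs, its median rise on a linear scale was 0.528 of theirs (199 genes, bootstrap 95% interval 0.456 to 0.569, genes taken as independent), against 1.19 and 1.02 for replicates 2 and 3. A compressed scale over the whole signal range of the array after 1 is argued against, as its spread over little-changed genes was 1.05 times that of the other arrays. The bright end was not examined alone, and whether noise in dim genes widened this spread was not tested, so compression of bright signals stays open. A candidate explanation is that some cells on the array after 1 had not yet changed, which should shrink falls as well. On the log2 scale falls were smaller there (median -0.61 against -1.53 in the other pairs, with -0.93 against -1.29 for replicate 2 and -1.24 against -1.31 for replicate 3), but the linear fractions of falling genes, on which the test was set beforehand, were 0.553 (0.449 to 0.799), 0.481 and 0.511 for replicates 1, 2 and 3. By the rule set beforehand this outcome counts against the explanation, as 0.553 does not lie below 0.481 and 0.511. The smaller log2 falls go with it. The linear fractions cannot separate the pairs, because those of falling genes were low in all 3. Those of replicates 2 and 3 also divide by a mean that holds the replicate 1 pair. Rising fractions of 1.19 and 1.02 therefore do not show that these pairs kept the full size of their rises. The explanation stays open.

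With 6 arrays, 10 divisions into 3 and 3 exist, too few for a share under 0.05. The real division gave 134 higher and 64 lower genes, and the highest of the others gave 0 of each, so 1 of 10 reached the real count in each direction. Of these divisions, 4 part all replicate pairs as the real one does, and the other 3 of them gave 0 as well. A difference between print blocks is argued against as the whole cause of the calls. Their spread over the 24 print blocks had a permutation p of 0.57 (10000 permutations), and the fullest block held 6.06% of them. This test does not address position within a block.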
